A study of Mus musculus with 8 samples.

How the data were processed

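RNA of sorted mouse bone marrow promyelocytes was amplified in 2 rounds, labelled with Cy3 and hybridised to single-colour Agilent arrays, 8 in all on 3 slides. A group of 3 arrays held preleukaemic PML/RARA early promyelocytes and a group of 5 arrays held leukaemic PML/RARA promyelocytes with Flt3-ITD. The first slide, described by one platform table, held 3 arrays, and the other slides, described by a second platform table, held 5. Groups were taken from the labels.

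The authors deposited per-array files in log2 units, which hold the logarithm of an uncorrected spot signal, since the values raised back lay within 0.01 of a multiple of 0.5 for 99.997% to 100% of the spots of signal under 1000, with no background column and no detection flags. The authors also deposited log2 values that were quantile-normalized over all 8 arrays together, as the tables' shared quantiles show, and per the labels limma was used, with no version given. Quantile normalization of the uncorrected log2 signal gave the authors' values with a correlation across probes of 1.000 and an SD of the difference of 0.00281. The signal column and the feature extraction version are not stated.

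The choices described here were made before the data were examined, except where stated otherwise. The first choice of signal, a processed signal scaled to the 75th percentile, was not in the files, so the fallback fixed beforehand was used. Signals were corrected with normexp (offset 50), spots of one probe were averaged, and the arrays were quantile-normalized. The offset compresses folds near background, so folds of genes close to the floor are understated. Probes were kept where the signal exceeded the 95th percentile of the 153 negative-control spots on every array of at least 1 group. That percentile lay between 19.0 and 40.0 on the linear scale, and 77.1% to 98.3% of probes exceeded it. The number of arrays limits the precision of every value.

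Of 41174 probes that both platform tables hold, 33462 had 1 gene symbol, 45 had several, 26 were named for different genes by the tables and 7641 had none. Names came from a GRCm38.p6 gene table, through gene ID for 32498 probes, symbol for 600, accession for 243 and synonym for 119, and from the platform table alone for 2. The build was used for gene names, neighbours and chromosomes. The filter kept 33696 probes, 28312 of them with 1 symbol. Each of the 17327 genes tested was represented by its brightest kept probe. Of these genes 7320 had several kept probes, and 185 of them had probes called in both directions.

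Genes were tested with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, in a model with group and platform table as fixed terms and the replicate as a random block, and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. All tests were 2-sided and all differences are leukaemic minus preleukaemic. A standard error (SE) is that of the log2 fold change. The replicate was the leukaemia (n = 3) or the preparation (n = 2), and the labels do not say how many animals each comes from. The estimated block correlation was negative (-0.44), so preparation #4 and leukaemias 1127/4 and 1087/5, with 2 arrays each, weigh more in the fit than #2 and 1020/4. Fitted folds can therefore differ from the difference of the group means. The p values of this fit rest on 5 residual degrees of freedom that count arrays, which overstates the number of independent samples, and not on the spread between preparations and leukaemias alone. The same test was run with the second 1087/5 sample as a replicate of its own, where the block correlation was 0.43, and with repeats averaged after removing the platform effect, on 3 residual degrees of freedom. The averaged fit does not count the error of the platform effect removed beforehand. No paired analysis was possible because the labels pair no preparation with a leukaemia.

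Named genes followed a fixed rule. It took the 10 largest rises and 10 largest falls among genes past the threshold, above background on every array and with replicates not overlapping, up to 4 in each direction that were not above background on any array of a group, every measured gene of the sort gate and construct and sex-linked lists, and up to 4 members of each other list with the smallest adjusted p, plus members among the largest changes. Unnamed clones were skipped, 1 rising and 1 falling. The rule gave 153 genes, of which 144 were called and 107 were also called with the 1087/5 samples separate. Of the 34 fixed gene lists, 23 hold cell programmes, 8 hold markers of other cell types, 1 is technical (immediate early and heat shock genes) and 2 are checks that were not tested as sets. Lists were tested with cameraPR (preset correlation 0.01), adjusted over the 32 lists, and checked with fry and with camera at an estimated correlation. Each list also got its count of members adjusted over the list alone.

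Alternatives covered the normalization, the offset (16), the filter, the platform and slide terms, the treatment of repeats, each array table alone, each replicate left out, the probe per gene, the variance model, the thresholds and the set test. The variants without a block, with a block correlation of 0.5, without the third slide, with 75th percentile scaling and with a filter at 4 times the negative controls were chosen after seeing the data.

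The procedure was tested on simulated data with 17327 genes, 200 of them changed. With independent arrays it called 54% of genes changed 2-fold and 89% of those changed 4-fold, with 24 false calls, and 7.13% of unchanged genes had an unadjusted p under 0.05. With the 1087/5 samples separate these values were 47%, 87%, 14 and 5.17%, and with repeats averaged 26%, 75%, 6 and 7.74%. Where repeat arrays shared 0.5 of the variance, the percentages for 2-fold and 4-fold changes were 39% and 80% for the blocked fit (9 false calls), 41% and 78% with the 1087/5 samples separate (8 false calls) and 18% and 66% with repeats averaged (2 false calls). Where the 1087/5 samples were independent and the duplicates shared 0.5 of the variance, they were 45% and 79% (11 false calls), 32% and 74% (2 false calls) and 22% and 71% (10 false calls). In these simulations with shared variance, in order, 5.29% and 6.37% of unchanged genes had an unadjusted p under 0.05 in the blocked fit. These values were 5.78% and 4.83% with the 1087/5 samples separate, and 6.79% and 7.45% with repeats averaged. In each case the sign was wrong for 0 genes, the shifted list was called, and 0 of 30 unchanged lists were called. No simulation gave repeat arrays a negative correlation like the -0.44 of the real fit. Each changed 200 genes, while the real fit called 5791. The simulations therefore do not measure the false calls of the real fit. Other computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9. No column of values was left unused.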

Results

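Gene expression was measured in mouse bone marrow promyelocytes, the granulocyte precursors that accumulate in acute promyelocytic leukaemia, with single-colour oligonucleotide arrays. PML/RARA is the fusion protein of that leukaemia, joining a nuclear body protein to a retinoic acid receptor, and Flt3-ITD is a constitutively active form of the receptor tyrosine kinase FLT3. The preleukaemic group held early promyelocytes sorted from PML/RARA transgenic mice aged 3 weeks and 5 days, of both sexes mixed, in 2 preparations (#2 and #4) measured on 3 arrays. The leukaemic group held promyelocytes of 3 leukaemias (1127/4, 1087/5 and 1020/4) measured on 5 arrays. These leukaemias arose after PML/RARA marrow was transduced with a Flt3-ITD retrovirus and transplanted, were passaged serially, and were sorted for GFP, KIT, GR1 and CD34 from female mice over 12 weeks old. Preparation #4 and leukaemia 1127/4 each had a technical duplicate, and leukaemia 1087/5 had a second array that its label calls a biological replicate. The replicates were thus 2 preparations and 3 leukaemias, and their repeat arrays entered the test as blocks, which did not make the test stricter, as given with the counts. The groups also differed in age, sex, sort gate and passage through transplantation, so each difference is one between the groups as they were sampled. Slide 3 held repeat arrays of leukaemias 1127/4 and 1087/5 and no preleukaemic array. The platform term of the test treats slides 2 and 3 alike, so an effect of slide 3 can enter the group differences. With slide as a fixed block 3955 genes passed, against 5791 in the fit reported. Between 77.1% and 98.3% of the probes of an array exceeded the negative-control spots, and the number of arrays limits the precision of every value.

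The design asks how leukaemic promyelocytes carrying PML/RARA and Flt3-ITD differ in expression from preleukaemic early promyelocytes carrying PML/RARA alone. In the blocked fit the largest rise was that of Cyp2a5, a cytochrome P450 of xenobiotic metabolism, with a log2 fold change of 8.03 (SE 1.06, adjusted p = 0.0017) and levels of 14.31 in 1127/4, 16.10 in 1087/5 and 11.27 in 1020/4. With repeats averaged the rise of Thbs4 (7.50) exceeded that of Cyp2a5 (7.44). Thbs4, an extracellular matrix thrombospondin, rose 200-fold, a log2 fold change of 7.64 (SE 0.16, adjusted p = 5.07e-07). Ngp, a protein of neutrophil granules, rose by 6.85 (SE 0.53, adjusted p = 0.00015), Cd33, a sialic acid-binding receptor of myeloid cells, by 5.59 (SE 0.18, adjusted p = 2.11e-06), and the calcium-binding protein S100a6 by 6.12 (SE 0.18, adjusted p = 1.24e-06). The largest fall was that of Ifi202b, an interferon-inducible gene of the p200 family, with a log2 fold change of -6.82 (SE 0.19, adjusted p = 1.24e-06). Klf4, a transcription factor of monocytes, changed by -5.96 (SE 0.51, adjusted p = 0.000233), and the lysosomal protease gene Ctss by -5.67 (SE 0.15, adjusted p = 1.02e-06).

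The other large rises above background on every array were those of Olfml2b at 6.84 (SE 0.20), the ectonucleotidase Nt5e at 6.40 (SE 0.21), the p53 target Perp at 5.75 (SE 0.52), the chitinase-like gene Chil4 at 5.42 (SE 1.26, adjusted p = 0.0674 with the 1087/5 samples separate) and Cyp2a22 at 5.30 (SE 1.14). The other large falls were those of the immediate early gene Fosb at -6.26 (SE 0.98), Tsix at -6.14 (SE 0.42), the adhesion receptor Adgrg7 at -5.64 (SE 0.12), Ifi209 at -5.58 (SE 0.10), the insulin-like growth factor binding protein Igfbp4 at -5.25 (SE 0.80), Ifi204 at -4.91 (SE 0.14) and the surface glycoprotein Cd24a at -4.83 (SE 1.35, adjusted p = 0.132 with the 1087/5 samples separate). Leukaemic replicates were not alike for all of these. For Fosb the leukaemic level was 6.74 in 1127/4, 8.33 in 1087/5 and 11.17 in 1020/4, against 13.64 ± 0.03 (SD, n = 2) in the preleukaemic preparations, on the normalized log2 scale. For Thbs4 the levels were 6.09 ± 0.01 (SD, n = 2) and 13.59 ± 0.31 (SD, n = 3). Among genes not well above background on any preleukaemic array, Nutm1 was at least 2.98-fold higher (adjusted p = 0.00036), Slc1a3 at least 2.33-fold (adjusted p = 0.0195, or 0.304 with the 1087/5 samples separate), Six6 at least 1.59-fold (adjusted p = 0.017, or 0.236) and Cep295nl at least 1.5-fold (adjusted p = 0.00645, or 0.0809). In the opposite direction, not well above background on any leukaemic array, Gja1 was at least 1.69-fold lower (adjusted p = 0.0005), Spin4 at least 1.25-fold (adjusted p = 0.0136, or 0.0894) and Cyp2r1 at least 1.24-fold (adjusted p = 0.0199, or 0.116).

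**Figure D1:**
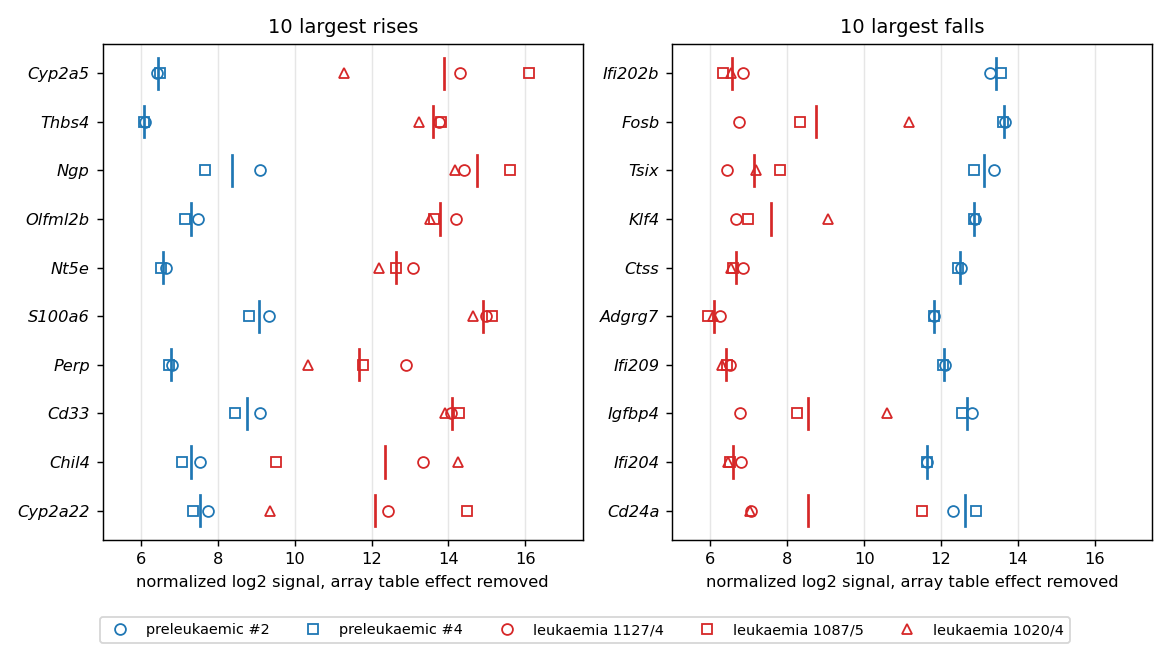
Normalized log2 signal, with the effect of the array table removed, of the 10 genes with the largest rise and the 10 with the largest fall in each of the 2 preleukaemic preparations and 3 leukaemias, where each symbol is 1 replicate with its repeat arrays averaged and each bar is a group mean. The leukaemic symbols of a gene lie on one side of the preleukaemic ones, tightly for Thbs4 and Ifi209 and widely spread for Cyp2a5, Fosb and Cd24a.

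In all, 5791 of 17327 genes tested passed an adjusted p of 0.05 in limma, 3072 higher and 2719 lower in the leukaemic group, and 1984 of them changed at least 2-fold. The estimated correlation between repeat arrays was negative (-0.44), which gives the repeated replicates more weight. The blocks thus made the test more liberal than taking every array as independent, where 2688 genes passed. With 1 replicate left out the estimated correlation lay between -0.71 (without leukaemia 1127/4) and -0.03 (without leukaemia 1087/5). Simulated independent arrays gave an estimate of -0.20, so part of the negative value can come from the estimation itself. With the second 1087/5 array as a replicate of its own 1918 genes passed, 943 higher and 975 lower, and all 1918 were also in the set of 5791 with the same sign. With repeat arrays averaged after removing the array table effect 2819 genes passed, in a fit that leaves out the error of the removed effect. The blocked, separate and averaged counts shared 1813 genes. Replicates of the groups did not overlap for 9492 of the 17327 genes tested (54.8%), where chance gives 20% for interchangeable replicates. These replicates are not interchangeable, since the groups lie unevenly over array tables and slides. Error of the removed array table effect can therefore add to the share, and genes can move together. The contrast with 20% is no test. The count was 2428 within the 3-array table and 184 within the 5-array table, and it fell to 132 without preparation #4, 3421 without leukaemia 1127/4 and 3733 without leukaemia 1087/5. The 3-array table holds 1 leukaemic sample (1127/4) and the 5-array table holds 1 preleukaemic sample (#4), each assumed to vary like the other group, as is the 1 preparation left without #4. The tables share these replicates, so they are no independent check of each other, and list medians within them are given without a test. Genes described as changed and given with a fold change passed with the 1087/5 samples together and separate, unless a second adjusted p is given for the separate count, while genes that only spell out a count were judged with these samples together. With repeats averaged, 7 named genes that passed both of these counts did not pass, namely Fosb (adjusted p = 0.0548), Tapbp (0.0555), Igfbp4 (0.058), Prtn3 (0.0582), Dusp2 (0.0654), Dusp1 (0.0658) and Cyp2a22 (0.0894). Averaging also moved the fold change of 14 named genes by more than 1.5-fold towards 0, among them Prtn3, and otherwise to 7.44 for Cyp2a5, 4.11 for Cpa3, 4.90 for Perp, 4.55 for Cyp2a22, 3.94 for Gata2, 2.20 for Chac1, 1.73 for Itgal, -4.89 for Fosb, -5.29 for Klf4, -4.14 for Igfbp4, -4.09 for Cd24a, -3.56 for Fcnb and -2.17 for Dusp1. Genes named outside the fixed rule, to spell out counts of 5 or fewer, were chosen after their values were seen.

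Of the 7 measured genes of the sort gate and of the construct, 3 rose and none fell, also when adjusted over the list alone. Rara, whose coding sequence the fusion contains in part, rose by 2.60 (SE 0.21, adjusted p = 0.000173), Cd34, a progenitor surface marker and part of the leukaemic gate, by 1.45 (SE 0.25, adjusted p = 0.0051, adjusted p = 0.0552 with the 1087/5 samples separate), and Ly6c1, a relative of the GR1 antigen, by 0.55 (SE 0.14, adjusted p = 0.0204, adjusted p = 0.069 with the 1087/5 samples separate). Kit had a log2 fold change of -0.08 (SE 0.44, adjusted p = 0.9), Flt3 of 0.40 (SE 0.17, adjusted p = 0.102), Pml of 0.33 (SE 0.26, adjusted p = 0.357) and Ly6c2 of 0.09 (SE 0.17, adjusted p = 0.709), so none of these passed. Whether the probes of Rara, Pml and Flt3 lie in the part carried by the constructs is not given in the sources used here. All 5 sex-linked genes measured fell, also when adjusted over the list alone. The X-inactivation RNA Xist changed by -3.62 (SE 0.14, adjusted p = 4.17e-06) and its antisense RNA Tsix by -6.14. The Y-linked genes Eif2s3y, Kdm5d and Uty changed by -3.90 (SE 0.19), -1.78 (SE 0.10) and -0.34 (SE 0.08, adjusted p = 0.116 with the 1087/5 samples separate) between leukaemias labelled female and preparations of both sexes, and the labels do not say whether female describes the transplanted mouse or the donor of the marrow. Eif2s3y exceeded the negative controls on 3 of the 5 leukaemic arrays, Kdm5d and Xist on 4 and Uty on 1.

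**Figure D2:**
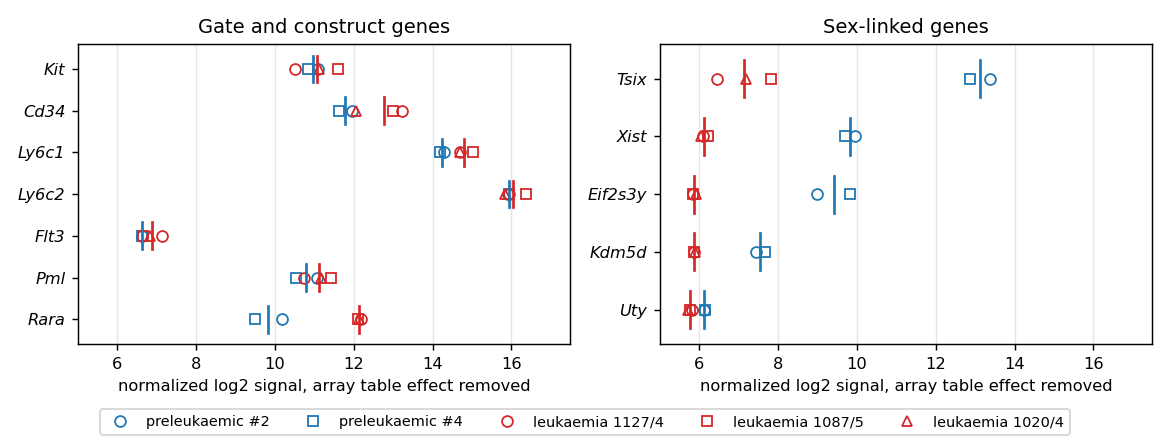
Normalized log2 signal, with the effect of the array table removed, of the measured genes of the sort gate and construct and of the sex-linked genes in each of the 2 preleukaemic preparations and 3 leukaemias, where each symbol is 1 replicate and each bar is a group mean. The leukaemias lie above the preleukaemic preparations for Rara and below them for Tsix, Xist, Eif2s3y and Kdm5d, and both groups overlap for Kit.

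Genes of the secondary and tertiary granules, which neutrophils fill as they mature, rose as a group. Of 35 measured members 18 rose, 5 fell (Cybb, Ltb4r1, Lyst, Il1b and Mmp8) and 12 did not pass, or 20 rose and 6 fell when adjusted over the list alone. The median log2 fold change was 1.38, with a camera adjusted p of 7.65e-06 and an adjusted p = 0.178 with an estimated correlation. The list's median was 1.07 within the 3-array table and 1.38 within the 5-array table. Besides Ngp, Olfm4 rose by 3.44 (SE 0.25), the calprotectin subunit S100a8 by 2.34 (SE 0.14) and the peptidoglycan receptor Pglyrp1 by 1.80 (SE 0.09). Primary granule genes, made earlier in promyelocytes, did not pass as a group (camera adjusted p = 0.84), and of 20 measured 3 rose (Lyz2, Cst7 and Serpinb1a) and 3 fell (Fcnb, Prtn3 and Elane), also when adjusted over the list alone. Lysozyme Lyz2 rose by 2.19 (SE 0.13), while the serine protease gene Prtn3 changed by -3.83 (SE 0.61) and the ficolin gene Fcnb by -4.21 (SE 0.48).

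Myeloid transcription factors moved in both directions. Of 39 measured 14 rose and 12 fell (16 and 12 adjusted over the list alone), with a median of 0.01 and a camera adjusted p of 0.469. Ets2 rose by 2.36 (SE 0.11), the retinoid X receptor gene Rxra by 1.89 (SE 0.19) and Cebpd by 1.20 (SE 0.10). Among stem and progenitor genes 5 of 31 rose (Gata2, Erg, Esam, Prdm16 and Zfpm1) and 10 fell, with the same counts adjusted over the list alone. Hoxa9, a homeobox gene of progenitors, changed by -3.49 (SE 0.14), Hlf by -3.42 (SE 0.20) and Satb1 by -2.79 (SE 0.21), while Gata2 rose by 4.71 (SE 0.39) and Erg by 1.59 (SE 0.13). This list had a median of -0.13 and just missed the threshold (camera adjusted p = 0.0536), and it passed it in 15 of the 25 other settings.

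Cell cycle genes were lower in the leukaemic promyelocytes. Of 40 measured genes of G2 and mitosis none rose and 23 fell (26 adjusted over the list alone), with a median log2 fold change of -0.67, a camera adjusted p of 2.18e-05 and an adjusted p = 0.728 with an estimated correlation. That median was -0.51 within the 3-array table and -0.88 within the 5-array table. The kinetochore motor gene Cenpe changed by -2.25 (SE 0.24), the spindle checkpoint kinase gene Ttk by -1.63 (SE 0.19), Hmmr by -1.40 (SE 0.19) and Cdca8 by -0.96 (SE 0.10). Of 37 genes of G1 and S phase 4 rose (E2f8, Ung, Tyms and E2f1) and 15 fell (4 and 16 adjusted over the list alone), with a median of -0.36, a camera adjusted p of 0.0113 and an adjusted p = 0.393 with an estimated correlation. The G1 and S median was -0.26 within the 3-array table and -0.35 within the 5-array table. Thymidine kinase Tk1 changed by -3.01 (SE 0.30), the DNA polymerase gene Pola1 by -2.10 (SE 0.27), Gins1 by -1.36 (SE 0.13) and Rfc4 by -1.06 (SE 0.12).

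Ribosome biogenesis genes and targets of MYC were lower as a group with camera as well, though not with fry. Of 42 measured 1 rose (Nop16) and 15 fell (1 and 16 adjusted over the list alone), with a median of -0.24, a camera adjusted p of 0.0268 and an adjusted p = 0.797 with an estimated correlation. Nucleolin Ncl changed by -1.47 (SE 0.15), Nop58 by -1.32 (SE 0.21), ornithine decarboxylase Odc1 by -1.01 (SE 0.09) and Tsr1 by -0.73 (SE 0.12). Its median was -0.23 within the 3-array table and -0.31 within the 5-array table. The call of this list was lost in 7 of the 25 other settings, among them the 3-array table alone and the fit without preparation #4. Among the lists called it was also the only one that fry did not call (fry adjusted p = 0.0984). Genes of ribosomal proteins did not pass as a group (median -0.01, camera adjusted p = 0.958). Of 47 measured, 3 rose (Rpl22, Rps9 and Rps27) and 2 fell (Rps24 and Rpl5), or 3 and 1 adjusted over the list alone. Rpl22 rose by 0.86 (SE 0.12), and Rps24 changed by -0.84 (SE 0.20, adjusted p = 0.164 with the 1087/5 samples separate), on a probe whose direction another probe of the gene did not share.

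Respiratory chain genes were lower and part of the genes of glycolysis and hypoxia were higher. Of 49 genes of oxidative phosphorylation none rose and 27 fell (31 adjusted over the list alone), with a median of -0.40, a camera adjusted p of 0.000186 and an adjusted p = 0.717 with an estimated correlation. The respiratory median was -0.31 within the 3-array table and -0.44 within the 5-array table. Ndufa9 of complex I changed by -0.94 (SE 0.11), Sdha of complex II by -0.84 (SE 0.11), Sdhc by -0.74 (SE 0.10) and the cytochrome oxidase gene Cox5a by -0.70 (SE 0.11). This call was lost without preparation #4 (adjusted p = 0.0776). Of 32 genes of glycolysis and hypoxia 12 rose and 3 fell (Pgam1, Ldha and Gapdh; 13 and 3 adjusted over the list alone), with a median of 0.22, a camera adjusted p of 0.0124 and an adjusted p = 0.797 with an estimated correlation. Ndrg1 rose by 2.90 (SE 0.18), hexokinase Hk3 by 2.74 (SE 0.10) and the oxygen-sensing prolyl hydroxylase genes Egln3 and Egln1 by 1.82 (SE 0.22) and 1.21 (SE 0.12). Ndrg1, Egln1 and Egln3 are known to respond to hypoxia. The 3 genes that fell encode enzymes of glycolysis, as does Hk3, which rose, so such enzymes moved in both directions. The median was 0.18 within the 3-array table and 0.33 within the 5-array table. This call was lost in 4 of the 25 other settings, 1 array per replicate, genes above background on every array, within the 3-array table and without preparation #4 (adjusted p = 0.209).

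Immediate early and heat shock genes, a list fixed as a sign of how cells were handled, were lower in the leukaemic group. Of 24 measured 2 rose (Hspb1 and Fos) and 16 fell (2 and 17 adjusted over the list alone), with a median of -0.90, a camera adjusted p of 0.000192 and an adjusted p = 0.591 with an estimated correlation. The handling list's median was -0.73 within the 3-array table and -0.90 within the 5-array table. Besides Fosb, the phosphatase gene Dusp1 changed by -2.99 (SE 0.42), Atf3 by -2.46 (SE 0.24) and the heat shock gene Hspa1a by -2.09 (SE 0.22). Genes of MAPK feedback share Fosb, Fos, Egr1 and Ier3 with this list. Of 23 measured 4 rose (Myc, Epha2, Fos and Etv4) and 7 fell, with the same counts adjusted over the list alone, and the list did not pass (median -0.18, camera adjusted p = 0.373). Spry2 changed by -3.72 (SE 0.30), Dusp2 by -2.63 (SE 0.47) and Egr1 by -1.57 (SE 0.20).

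Genes of the FLT3 and STAT5 response did not pass as a group (median 0.54, camera adjusted p = 0.275), although 13 of 27 rose and 4 fell (Ccnd2, Dusp1, Gadd45g and Osm; 15 and 4 adjusted over the list alone). The STAT5 feedback gene Cish rose by 3.63 (SE 0.29) and cyclin D3, Ccnd3, by 1.41 (SE 0.15), while cyclin D2, Ccnd2, changed by -3.33 (SE 0.17) and Gadd45g by -1.83 (SE 0.19). Of 25 retinoid pathway genes 6 rose and 2 fell (Dok2 and Crabp1), also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.385). Besides Rara and Rxra, Dok2 changed by -1.28 (SE 0.16) and Crabp1 by -0.84 (SE 0.20, adjusted p = 0.168 with the 1087/5 samples separate). Of 30 p53 targets 9 rose and 4 fell (Btg2, Plk2, Gtse1 and Mdm2; 11 and 5 adjusted over the list alone), with a camera adjusted p of 0.275. Trp53inp1 rose by 2.91 (SE 0.25), Perp by 5.75, and the BH3-only gene Bcl2l11 by 1.48 (SE 0.17) on a probe whose direction another probe did not share. Plk2 changed by -0.77 (SE 0.09).

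Apoptosis regulators (23 measured) held 5 that rose (Bcl2l11, Bbc3, Birc3, Bmf and Casp6) and 2 that fell (Hrk and Casp1), also when adjusted over the list alone, with a camera adjusted p of 0.585. Bbc3 rose by 1.02 (SE 0.13), Casp6 by 0.61 (SE 0.14, adjusted p = 0.0566 with the 1087/5 samples separate), and Hrk changed by -1.26 (SE 0.24). Of 22 genes of PML nuclear bodies and SUMO 4 rose (Sp100, Pias4, Senp7 and Daxx) and 5 fell (Atrx, Blm, Wrn, Senp5 and Senp2), also when adjusted over the list alone, with a camera adjusted p of 0.958. Sp100 rose by 1.16 (SE 0.11) and Daxx by 0.44 (SE 0.10, adjusted p = 0.0927 with the 1087/5 samples separate), while Atrx changed by -1.92 (SE 0.22) and Blm by -0.74 (SE 0.19, adjusted p = 0.114 with the 1087/5 samples separate). Of 34 chromatin genes 5 rose (Hdac7, Asxl1, Dnmt1, Ezh1 and Hdac9) and 11 fell (6 and 11 adjusted over the list alone), with a camera adjusted p of 0.646. Tet1 changed by -1.94 (SE 0.20), Phf6 by -1.39 (SE 0.23, adjusted p = 0.0633 with the 1087/5 samples separate), Idh1 by -1.32 (SE 0.23, adjusted p = 0.0652 with the 1087/5 samples separate) and Idh2 by -0.67 (SE 0.12). Of 29 genes of the unfolded protein response 8 rose and 3 fell (Dnajc3, Hsp90b1 and Sec61b; 8 and 4 adjusted over the list alone), with a camera adjusted p of 0.958 and a median of -0.10 beside a mean of 0.19. Chac1 rose by 2.87 (SE 0.66, adjusted p = 0.0919 with the 1087/5 samples separate), Sesn2 by 1.60 (SE 0.29, adjusted p = 0.0917 with the 1087/5 samples separate) and Edem1 by 0.86 (SE 0.13), and Sec61b changed by -0.46 (SE 0.10, adjusted p = 0.094 with the 1087/5 samples separate). Of 20 cholesterol synthesis genes 2 rose (Srebf2 and Tm7sf2) and 1 fell (Insig1), or 1 and 1 adjusted over the list alone, with a camera adjusted p of 0.958. Srebf2 rose by 0.84 (SE 0.14), Tm7sf2 by 0.37 (SE 0.11, adjusted p = 0.147 with the 1087/5 samples separate), Insig1 changed by -1.03 (SE 0.22, adjusted p = 0.108 with the 1087/5 samples separate) and Mvd had a value of -1.05 (SE 0.36).

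Genes of antigen presentation by MHC class II passed as a list (median -0.35, camera adjusted p = 0.000869, adjusted p = 0.717 with an estimated correlation). The class II median was -0.48 within the 3-array table and -0.29 within the 5-array table. Of 11 measured none rose and 3 fell (Ctss, Ifi30 and H2-Oa), or 1 rose and 4 fell when adjusted over the list alone. Ifi30, a lysosomal thiol reductase, changed by -2.54 (SE 0.25) and H2-Oa by -1.69 (SE 0.41, adjusted p = 0.0831 with the 1087/5 samples separate), while the invariant chain Cd74 had a value of 0.60 (SE 0.20). Ctss and Ifi30 act in lysosomes and are not class II molecules, and Ctss is also on the monocyte list, which was called downwards too. Without genes held by more than 1 list the adjusted p was 0.18. Of 21 MHC class I genes 2 rose (Tapbp and H2-T24) and 7 fell (3 and 10 adjusted over the list alone), with a camera adjusted p of 0.102. B2m changed by -1.99 (SE 0.13), on a probe whose direction another probe did not share, Psmb8 by -1.34 (SE 0.13) and Psmb10 by -0.97 (SE 0.17), and Tapbp rose by 1.56 (SE 0.20). Of 40 genes of the type I interferon response 5 rose (Ddx58, Irf7, Irf9, Isg20 and Dhx58) and 10 fell (5 and 11 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 0.331. Ifi47 changed by -2.52 (SE 0.29) and Gbp3 by -2.25 (SE 0.15), and Ddx58 rose by 2.22 (SE 0.15). Of 37 chemokine and adhesion genes 10 rose and 9 fell (11 and 10 adjusted over the list alone), with a camera adjusted p of 0.302. Besides Cd33, the integrin gene Itgal rose by 2.40 (SE 0.29) and Cd53 by 1.57 (SE 0.17), while Jaml changed by -0.97 (SE 0.10).

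**Figure D3:**
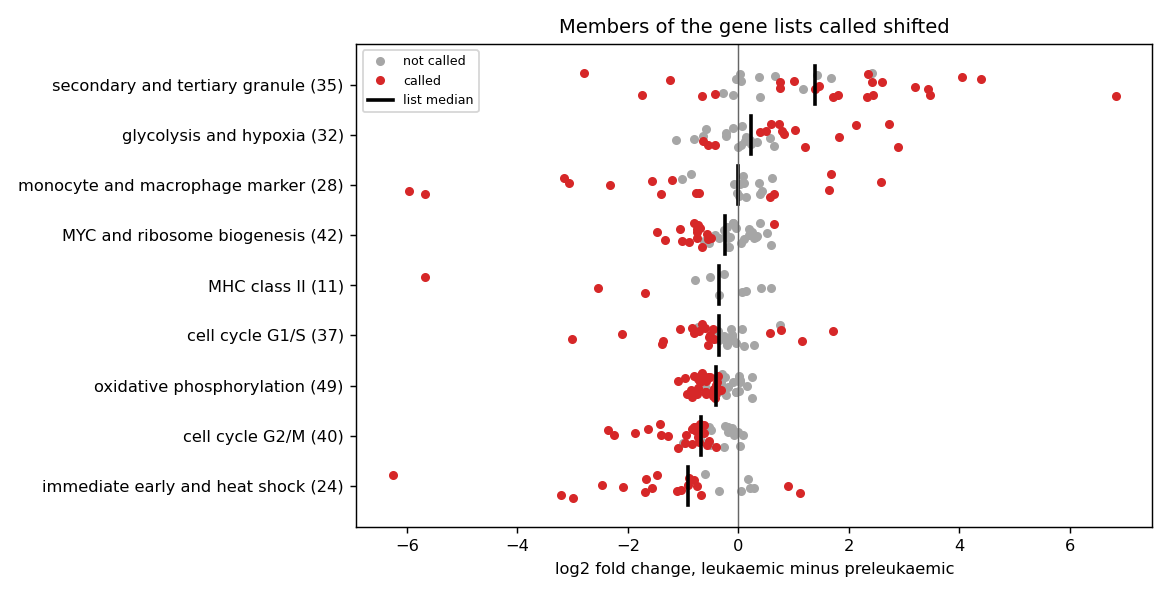
Log2 fold changes, leukaemic minus preleukaemic, of the measured members of the 9 gene lists called shifted, with the number of members after each name, members past the test in red, the others in grey and the list median as a bar. The secondary and tertiary granule list has the highest median (1.38) and the immediate early and heat shock list the lowest (-0.90), and each of the 9 lists holds members on both sides of 0.

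Markers of other cell types the gate could hold did not pass as groups, apart from those of monocytes and macrophages. Of 28 measured monocyte and macrophage markers 5 rose (Vcam1, Cd68, Adgre1, Mertk and Spic) and 10 fell (6 and 10 adjusted over the list alone), with a median of 0.00, a mean of -0.66, a camera adjusted p of 0.0182 downwards and an adjusted p = 0.717 with an estimated correlation. The monocyte median was 0.01 within the 3-array table and -0.12 within the 5-array table. Besides Klf4 and Ctss, Fcgr4 changed by -1.57 (SE 0.17) and Cd163 by -1.21 (SE 0.15). Without genes held by more than 1 list the adjusted p was 0.7. Of 20 mast cell, basophil and eosinophil markers 4 rose (Cpa3, Gata2, Mcpt8 and Alox15) and 2 fell (Cma1 and Prss34; 4 and 3 adjusted over the list alone), with a camera adjusted p of 0.408. The protease genes Cpa3 and Mcpt8 rose by 6.18 (SE 1.42, adjusted p = 0.113 with the 1087/5 samples separate) and 1.92 (SE 0.14), and Prss34 changed by -0.74 (SE 0.13, adjusted p = 0.11 with the 1087/5 samples separate). The Cpa3 level was 13.31 in 1127/4 and 11.76 in 1087/5, but 6.24 in 1020/4 against 6.33 ± 0.06 (SD, n = 2) in the preleukaemic preparations.

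Of 15 B cell markers 1 fell (Cd79b) and none rose, also when adjusted over the list alone, with a camera adjusted p of 0.584. Cd79b, part of the B cell receptor, changed by -4.72 (SE 0.15), while Vpreb1, Ebf1 and Dntt had values of 0.58 (SE 0.20), 0.58 (SE 0.20) and 0.32 (SE 0.12). Of 21 T and NK cell markers 6 rose and 4 fell (Gzmb, Cd4, Cd3d and Cd28; 8 and 5 adjusted over the list alone), with a camera adjusted p of 0.646. Gzmb changed by -0.90 (SE 0.18, adjusted p = 0.064 with the 1087/5 samples separate), Cd28 by -0.43 (SE 0.09, adjusted p = 0.073 with the 1087/5 samples separate), Cd5 by 0.72 (SE 0.16, adjusted p = 0.131 with the 1087/5 samples separate) and Cd8a by 0.80 (SE 0.17, adjusted p = 0.0651 with the 1087/5 samples separate). Of 19 erythroid markers 5 rose (Rhd, Gata1, Klf1, Epor and Ermap) and 4 fell (Tfrc, Tspan33, Car2 and Slc4a1; 6 and 4 adjusted over the list alone), with a camera adjusted p of 0.878. Rhd rose by 1.77 (SE 0.27), while Tspan33 changed by -1.06 (SE 0.16), Car2 by -0.94 (SE 0.09) and Slc4a1 by -0.77 (SE 0.11). Of 15 megakaryocyte markers 2 rose (Plek and Itga2b) and 2 fell (Itgb3 and Nrgn; 2 and 1 adjusted over the list alone), with a camera adjusted p of 0.585. Plek rose by 3.01 (SE 0.41), Itga2b by 1.53 (SE 0.35, adjusted p = 0.105 with the 1087/5 samples separate) and Nrgn changed by -0.32 (SE 0.10, adjusted p = 0.281 with the 1087/5 samples separate). The probe of Itgb3 gave -0.82 (SE 0.19, adjusted p = 0.111 with the 1087/5 samples separate), and another probe of the gene gave the opposite sign.

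Of 19 dendritic cell markers 1 rose (Runx2) and 5 fell (Tcf4, Clec9a, Ccr9, Cox6a2 and Xcr1; 3 and 6 adjusted over the list alone), with a camera adjusted p of 0.958. Runx2 rose by 1.62 (SE 0.08), Tcf4 changed by -1.85 (SE 0.11), Clec9a by -1.05 (SE 0.21, adjusted p = 0.0625 with the 1087/5 samples separate) and Ccr9 by -0.81 (SE 0.22, adjusted p = 0.237 with the 1087/5 samples separate). Of 19 markers of stroma and endothelium 4 rose (Spp1, Adipoq, Cxcl12 and Col1a2) and 2 fell (Tie1 and Kdr), also when adjusted over the list alone, with a camera adjusted p of 0.958. Osteopontin Spp1 rose by 4.66 (SE 0.14) and Col1a2 by 0.51 (SE 0.14, adjusted p = 0.225 with the 1087/5 samples separate), while the endothelial receptor gene Tie1 changed by -4.55 (SE 0.11) and Kdr by -1.14 (SE 0.15), on a probe whose direction another probe did not share.

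Of the 32 lists tested, 9 were called with the preset correlation of 0.01 and none with an estimated correlation, where the smallest adjusted p was 0.178 and 2 lists, secondary and tertiary granule and G1 and S phase, had an unadjusted p under 0.05. Rotation tests with fry ask whether the genes of a list move on balance in one direction and make no comparison with other genes. They called 18, among them all of these 9 but ribosome biogenesis and MYC targets. The median, the mean and the test did not share a sign for the lists of primary granules, myeloid transcription factors, ribosomal proteins, cholesterol synthesis, the unfolded protein response and markers of B cells, erythroid cells, monocytes, dendritic cells and stroma.

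Repeat arrays of one replicate showed how far single values can be trusted. Across the tested genes the duplicates of preparation #4 correlated at r = 0.990 with an SD of the log2 difference of 0.333, and those of leukaemia 1127/4 at r = 0.973 with an SD of 0.533, where each pair spans both array tables. With the array table effect removed the SD was 0.272 for each of these pairs, a value lowered by construction since the effect was estimated from the same pairs. The samples of leukaemia 1087/5 correlated at r = 0.972 with an SD of 0.545, while leukaemias 1087/5 and 1020/4 on one slide correlated at r = 0.977 with an SD of 0.496. Arrays of different groups correlated at r = 0.914 to 0.946. These correlations are across genes, which are not independent replicates. The 1087/5 samples lie on different slides of one table, where samples of different leukaemias on different slides had an SD of 0.556 to 0.645. Leukaemias 1127/4 on slide 1 and 1087/5 on slide 2, in different array tables, had an SD of 0.515, below that of the 1127/4 duplicates. Against 1020/4 on slide 2 and 1087/5 on slide 3 the same 1127/4 array had larger SDs, 0.606 and 0.581. Preparations #2 and #4 had an SD of 0.266 on slide 1, below that of the #4 duplicates, and 0.424 between slides 1 and 2. Repeat arrays were therefore not always closer than arrays of different replicates.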

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

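Probes without a single gene symbol were outside the gene comparison, and 1640 of 5384 such probes kept by the filter passed the same limma test, 635 higher and 1005 lower in the leukaemic group. They drew attention as signal in data that the gene comparison does not use, and no explanation was tested for them.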

How the results depend on the processing

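The settings without a block, with a block correlation of 0.5, with 75th percentile scaling, without the third slide and with a filter at 4 times the negative controls were chosen after seeing the data. The planned settings with processed signal and with separate background columns were not run, since the files hold no such columns. Of 5791 genes called, the count became 2819 with repeats averaged after removing the platform effect, 1090 with 1 array per replicate, 1918 with the 1087/5 samples separate, 2428 within the 3-array table, 184 within the 5-array table, 2688 without a block, 1184 at a block correlation of 0.5 and 10011 over 28312 probes tested singly. It was 1984 with a 2-fold minimum and 2363 at an adjusted p of 0.01. With slide as a fixed block it was 3955, 2025 higher and 1930 lower. With 75th percentile scaling it was 7332, 3549 higher and 3783 lower, so the larger share then fell. Leaving out 1 replicate gave 132 (without preparation #4) to 7242 (without leukaemia 1020/4), with 3421 without 1127/4, 3733 without 1087/5 and 4967 without preparation #2. Without #4, as within the 5-array table, 1 preparation is left, and the 3-array table holds 1 leukaemia, each assumed to vary like the other group. The cause was not tested.

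Of the 144 named genes called, 69 were called with 1 array per replicate, 33 within the 5-array table, 94 at a block correlation of 0.5, and 28 (without #4) to 144 with 1 replicate left out, 141 of them without preparation #2. The sign was the same in all 25 settings for 139, and 23 were called in all of them. The others were Rps24, at 0.42 with no filter, 0.29 above background on every array and 0.30 at 4 times the negative controls, Bcl2l11, at -0.14 with no filter and -0.14 above background on every array, B2m, at 0.29 at 4 times the negative controls, Itgb3, at 1.37 with probes averaged and 3.56 at 4 times the negative controls, and Kdr, at 0.20 with no filter. In each of these another probe entered the gene's value. Over named genes and settings 3121 results were the same, 624 lost the call, 29 gained it and 9 reversed.

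The 9 lists called became 14 within the 3-array table (4 up, 10 down), 18 with fry and 0 with camera at an estimated correlation, where 2 had an unadjusted p under 0.05. Among marker lists 1 was called, against 2 above background on every array, 2 within the 3-array table, 3 with fry, and 0 at 4 times the negative controls, with an estimated correlation or without shared genes. The direction reversed for the primary granule (adjusted p = 0.0478) and myeloid transcription factor (adjusted p = 0.0275) lists within the 3-array table, both downwards, and for the stroma and endothelium list above background on every array (adjusted p = 0.0117, upwards), none of which was called in the fit reported. The cause was not tested. Over lists and settings 825 results were the same, 42 gained the call, 25 lost it and 3 reversed. Repeat array correlations moved little with the filter and normalization settings, while removing the array table effect took the SD of the 1127/4 duplicates from 0.533 to 0.272, lowered by construction. Signal over background limits the folds of dim genes.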

Other observations

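The genes and chromosomes described here were chosen after their values were seen, and so were the tests of random placement, of the loss of all copies on chromosome 1, of genes with 1 kept probe, of the interferon list, of Y-linked genes, of the single 1020/4 array and of the other chromosomes, and every restriction to bright genes except that of the chromosome shifts of 1020/4 and 1087/5. Bright genes had a signal over 4 times the negative-control percentile on every array, or on every preleukaemic array for the chromosome 1 genes and the interferon list.

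These are single genes with a wide spread between the 3 leukaemias, on the normalized log2 scale. The stefin gene Stfa1 was at 6.22 in 1127/4, 11.90 in 1087/5 and 13.82 in 1020/4, against 6.34 in the preleukaemic preparations. The eosinophil ribonuclease gene Ear6 was at 12.74 in 1020/4 and at 7.27 and 6.89 in 1127/4 and 1087/5, against 8.25. Tal1, a transcription factor of blood stem and erythroid cells, was at 7.13 in 1127/4, 11.99 in 1087/5 and 13.30 in 1020/4, against 11.16. The protease gene Ctsc was at 6.52 in 1087/5 and at 11.91 and 11.04 in 1127/4 and 1020/4, against 11.81. The histidine decarboxylase gene Hdc was at 12.56 in 1127/4, 9.37 in 1087/5 and 7.07 in 1020/4, against 13.31. No difference between leukaemias was tested, and 1020/4 has 1 array.

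Among 91 large falls (log2 of -3 or lower), 4 lay within 25 neighbouring genes of chromosome 1, namely Gm37125, Ifi209, Ifi204 and Ifi202b, where the next highest chromosome held 2, and random placement reached this in a share of 0.0211 of 10000 draws. Gm37125 sits at the bound, with a fitted value of -3.05 (SE 0.48). Its preleukaemic mean was 9.24 and its leukaemic mean 7.16, with a leukaemic SD of 1.15 (n = 3). Placement was not tested without Gm37125. A variant under single probes is opposed by 4 other probes of Ifi204 and Ifi209 (median -2.88, 4 of 4 fell), though 2 genes have 1 kept probe and stay undecided. A lower type I interferon response as the whole cause is opposed by that list's median of -0.23 (SE 0.16, 40 genes). Over the list's 23 bright genes it was -0.23 with a larger SE of 0.26. Responses to other interferons were not tested. The related genes Aim2, Ifi211 and Ifi203 changed by -2.49, -1.42 and -1.35. The related gene Ifi207, between Ifi209 and Ifi204, had a value of 0.15 (SE 0.13). Loss of all copies of the whole stretch is opposed by 1 gene, Dusp23, at 0.10 (SE 0.18) and bright on every leukaemic array. It lies between Gm37125 and Ifi209, so it says nothing of a stretch without Gm37125. Ifi207 lies in such a stretch, with a mean of 7.39 in each group. It was not bright on every leukaemic array and did not count in this test. Loss of 1 of 2 copies lowers signal about 2-fold. As the whole cause it is opposed by Ifi204, Ifi209 and Ifi202b at -4.91 (SE 0.14), -5.58 (SE 0.10) and -6.82 (SE 0.19). Whether 1 copy was lost stays open. The median of -0.0409 (SE 0.0519) over the other 19 genes there rests on 15 dim genes that cannot show it. The 4 bright ones had a median of -0.96 (SE 0.65), but include Aim2 and Ifi211, related to the genes that fell. Losses of shorter stretches, a strain difference at this locus or signal shared between paralogues may account for the falls, and these were not tested.

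Xist and Tsix were lower in leukaemic samples that the labels call female, without saying whether this describes the recipient or the donor of the marrow. Male cells that kept a Y chromosome are opposed by the Y-linked genes, whose median was -1.78 (3 genes). X-linked genes other than these differed from autosomal genes by -0.0906 (median difference, 95% interval -0.138 to -0.0443, 591 genes) and among bright genes by -0.187 (95% interval -0.302 to -0.0614, 247 genes), which opposes a second active X chromosome, predicted to exceed 0.2. Loss of an active X chromosome's dose, predicted below -0.2, cannot be told apart from no loss, since the interval among bright genes includes that bound and genes near the floor dilute the value over all genes. Loss of the silenced X chromosome, silencing of Xist itself, or male cells that lost the Y chromosome may account for it, and the mixed sexes, age and passage of the groups stay open.

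Over all tested genes, those of chromosome 10 were higher in leukaemia 1020/4 (0.196 above the autosomal median) and those of chromosome 12 on both 1087/5 arrays (0.208 and 0.243), the largest shifts among 20 chromosomes and 5 leukaemic arrays, while camera over the chromosomes called none between groups (smallest adjusted p = 0.518). Probes near background are opposed by bright genes, whose smallest shift was 0.253, and a few neighbouring genes by blocks with a median above 0, 9 of 10 on chromosome 10 and 10 of 10 on chromosome 12. Block medians ran from -0.02 to 0.56 on chromosome 10 and from 0.10 to 0.30 on chromosome 12. The shift was thus uneven along chromosome 10. A single array as the source is opposed for chromosome 12 by the smaller of its shifts, 0.208, but stays undecided for chromosome 10, since 1020/4 has 1 array. A trend shared by many chromosomes is opposed for chromosome 12, whose shift among bright genes over both 1087/5 arrays exceeded the furthest other chromosome's by 0.165 (95% interval 0.0607 to 0.263), though on the first of these arrays alone chromosome 13 was further from 0 at -0.272, and it stays open for chromosome 10, which exceeded the X chromosome of 1020/4 by 0.0783 (95% interval -0.117 to 0.239). A gained chromosome copy in part of the cells may account for the shifts, which no measurement of DNA tested here.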
